A study of Homo sapiens with 25 samples.

How the data were processed

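Small RNA sequencing was analysed in 9 libraries of A2780 cells carrying an empty vector, a miR-450a vector or a miR-450b vector, 3 in each group. Per the labels' protocols, RNA was isolated with TRIzol and small RNA libraries were read as 50-cycle single reads on an Illumina HiSeq instrument. The values deposited by the authors are fractions, each the share of a mature miRNA or precursor in all miRNA reads of a library, per the file headers. Each column summed to 1. The aligner and miRNA annotation behind these shares are not given in the sources used here. The submitters' processing notes name TopHat and Cuffdiff for the series, with no version or role. The mature table had 1410 rows, 1033 of them human and 377 viral, with 934 rows in the table of precursors, 557 of them human. A mature miRNA made by several gene copies stands in a single row, and a star marks the lesser arm. Read totals were not given, so the depth is unknown, no interval or detection limit was computed, and a count-based test was not run. A share can rise because other miRNAs fall, and miR-199a, miR-199b and miR-214 held much of the reads in 2 of the 3 groups, so each count was also computed with another scaling.

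Shares were multiplied by 1000000 (reads per 1000000 miRNA reads, RPM) and analysed as log2(RPM + 10), so fold changes on this scale understate the change of low miRNAs. Rows with a mean of at least 10 RPM over the 9 libraries were kept, 403 human and 3 viral in the mature table and 281 human and 3 viral in the precursor table. A limma fit of all 9 libraries with an intensity trend (limma 3.58.1 in R 4.3.3) gave log2 changes, standard errors and Benjamini-Hochberg adjusted p-values for the 3 comparisons. Each comparison was adjusted over all rows tested, at a threshold of 0.05. Levels and shares of miR-450a and miR-450b were also compared with two-sided exact permutation tests, whose smallest p with 3 against 3 is 0.1. The 16 miRNA lists were fixed before the data were examined, and the 11 with at least 3 tested members were tested with camera at a preset correlation of 0.01 and an estimated one, and with fry. Camera and fry p-values were adjusted over the 11 lists of a comparison. Each tested arm of a listed miRNA counted as a member. Arms of the same hairpin and miRNAs of neighbouring genes are not independent, so counts of members are not counts of separate loci.

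The miRNAs named were chosen by a rule fixed before the data were examined. It took every arm of the cluster of the vectors, the 10 largest rises and 10 largest falls among miRNAs that passed the threshold and whose groups did not overlap, the 5 most abundant miRNAs, and the 2 most abundant members of each list. Precursors were the cluster members and the 3 largest rises and falls. Members of the lists named outside this rule for a comparison, such as miR-192, miR-9, miR-126 and the let-7 members named for the miR-450a vector, were chosen after their values were seen. The code was tested on simulated data made from the 406 mature rows, with 50 miRNAs changed at each size. For the miR-450a vector against the empty vector it recovered 74.0% of log2 changes of 1 and 98% of changes of 2, with 7 false calls. For the miR-450b vector against the empty vector it recovered 56.0% and 94.0%, with 5 false calls, and for the vectors against each other 66.0% and 98%, with 2. The simulations used the same means and spread and differed only in the rows and values drawn at random. These rates therefore do not rank the comparisons by sensitivity.

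Alternatives were pseudocounts of 1 and 100 RPM, no filter, a mean of at least 100 RPM, removal of the miR-450a and miR-450b rows, median-of-ratios scaling, limma without the trend, a fit of the compared groups only, the replicate number as a block, and leaving out each library in turn. The replicate block and median-of-ratios scaling were each also combined with an estimated correlation, neighbouring precursors were tested without pairs of the same miRNA number, and the cluster list was tested without the miR-450a and miR-450b arms, all chosen after seeing the data. Expected overlap between comparisons sharing the empty vector libraries came from 100 simulations of unchanged groups. Gene neighbours were read from the GRCh38.p14 gene table, where 270 of 281 tested human precursors matched a gene by symbol or a single older name, and the others were left out of the test of neighbours. Since the tables name no genome build, no coordinates are given. Python 3.11.15 and matplotlib 3.10.9 were used for summaries and figures. The mRNA sequencing and PAR-CLIP samples were not analysed here.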

Results

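MicroRNA (miRNA) abundance was measured by small RNA sequencing in A2780, an established human ovarian carcinoma cell line. The cells carried an empty lentiviral vector, a vector for miR-450a or a vector for miR-450b, with 3 libraries in each group. The values were relative frequencies, each the share of all miRNA reads of a library, and are given here as reads per 1000000 miRNA reads (RPM). The read totals were not given with the shares, so the sequencing depth behind each value is unknown. Between 670 and 890 of the 1410 rows of the mature table were above 0 in a library, and the 10 most abundant rows held 43.7% to 53.2% of its reads. The labels call the 3 libraries of a group biological replicates but do not say whether they came from separate transductions or cultures, so p-values measure the spread between these samples, which may be technical. The series also holds 12 mRNA sequencing samples and 4 Argonaute PAR-CLIP samples, which were not analysed here.

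The miRNAs named in the vectors belong to a cluster of neighbouring genes on the X chromosome (MIR450B, MIR450A1, MIR450A2, MIR542, MIR503 and MIR424 in the GRCh38.p14 gene table). miR-450a stood at 8967, 10075 and 20745 RPM in the miR-450a vector libraries. It stood at 317, 405 and 446 in the empty vector libraries and at 270.2, 504.1 and 445 in the miR-450b vector libraries. miR-450b stood at 547, 850.3 and 1544 RPM in the miR-450b vector libraries. It stood at 71.6, 72.4 and 131 in the empty vector libraries and at 207, 223.2 and 293 in the miR-450a vector libraries. miR-450a rose with its own vector by 4.96 ± 0.37 (log2, SE, adjusted p = 5.36e-07), and miR-450b rose with its own vector by 3.21 ± 0.39 (adjusted p = 1.35e-04). All 3 libraries of each vector group lay above the 3 empty vector libraries, and a two-sided exact permutation test gave p = 0.1 for both, the smallest p that 3 against 3 allows.

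With the miR-450b vector, miR-450a differed from the empty vector by 0.03 ± 0.37 on the log2 scale (adjusted p = 0.981). With the miR-450a vector, miR-450b was higher by 1.34 ± 0.39 (adjusted p = 0.0132). That call was lost with median-of-ratios scaling of the libraries, where the change was 0.85, and without miR-450a vector replicate 3, where it was 1.20 (adjusted p from 0.00294 to 0.0889 over the alternatives run). With a pseudocount of 100 RPM it was 0.84. Together miR-450a and miR-450b held 0.0506 ± 0.00978% of miRNA reads with the empty vector (SD, n = 3). They held 1.45 ± 0.640% with the miR-450a vector and 0.146 ± 0.0606% with the miR-450b vector (SD, n = 3). The exact permutation test against the empty vector gave p = 0.1 for each.

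Each precursor gives a main arm and a lesser arm that the table marks with a star. The main arm made up 92.04 ± 3.77% of miR-450a reads with the miR-450a vector and 94.0 ± 0.200% with the empty vector (SD, n = 3, exact permutation p = 0.4). For miR-450b it made up 95.6 ± 0.651% with the miR-450b vector and 99.3 ± 0.607% with the empty vector (SD, n = 3, exact permutation p = 0.1). The mature miR-450a sequence is shared by 2 gene copies, whose starred arms differ. miR-450a-1* stood at 936 ± 221.7 RPM with the miR-450a vector and 12.3 ± 2.63 with the empty vector. miR-450a-2* stood at 44.3 ± 7.54 and 12.4 ± 3.73 (SD, n = 3). Of the reads of both starred arms, miR-450a-1* held 95.3 ± 1.46% with the miR-450a vector, 39.5 ± 1.83% with the miR-450b vector and 50.2 ± 11.6% with the empty vector.

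**Figure D1:**
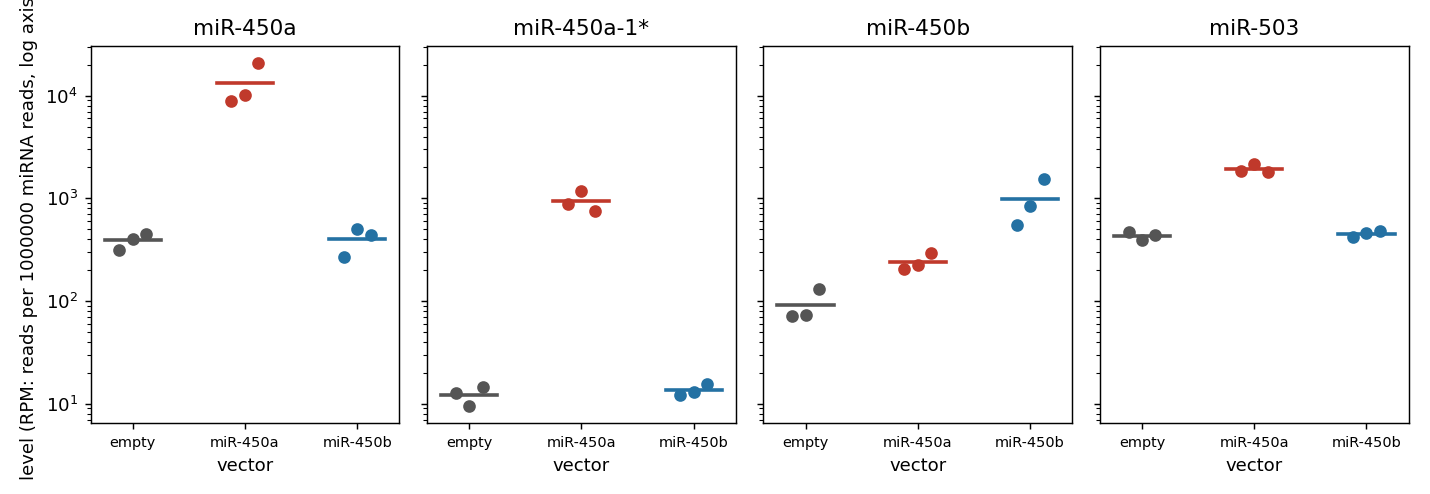
Level of miR-450a, miR-450a-1*, miR-450b and miR-503 in each library, in RPM on a log axis, with 1 point per library and a bar at the mean of each group of 3. miR-450a had means of 389 with the empty vector and 13262 with the miR-450a vector, and miR-450b of 91.7 with the empty vector and 980.4 with the miR-450b vector.

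The series concerns miR-450a in ovarian cancer, and this comparison asks which other miRNAs differ in cells that carry its vector. The miR-450a vector libraries differed from the empty vector libraries in most of the miRNAs tested. miR-199a, miR-199b and miR-214, which are expressed in mesenchymal cells, held 20.7 ± 4.14% of miRNA reads with the empty vector and 0.0464 ± 0.00735% with the miR-450a vector (SD, n = 3). With the miR-450b vector they held 22.2 ± 2.46%. miR-214-3p fell from 19710.0 ± 4958 to 26.8 ± 9.28 RPM, and miR-199a-5p from 46228 ± 10614 to 92.2 ± 43.6. miR-196b and miR-10b, which lie in HOX gene clusters, rose from 39.8 ± 20.3 to 8787 ± 1062 and from 135 ± 76.7 to 15830.2 ± 2314 RPM. In the same libraries a viral row, SV40 miR-S1-3p, stood at 63.8 ± 13.95 RPM, against 0.0889 ± 0.154 with the empty vector and 0.167 ± 0.289 with the miR-450b vector (SD, n = 3). These values leave it unsettled whether the miR-450a vector libraries hold A2780 RNA. Rises and falls with the miR-450a vector are therefore differences between libraries and cannot be read as effects of miR-450a.

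Of 406 mature miRNAs with a mean of at least 10 RPM, 225 passed an adjusted p of 0.05 in the limma fit, 150 higher and 75 lower with the miR-450a vector. The groups did not overlap for 235 miRNAs (57.9%, where chance gives 10%). With median-of-ratios scaling 49.5% of the calls were higher, against 66.7% as deposited, and the median log2 change of all miRNAs moved from 0.44 to -0.01. Among the largest rises, miR-296-3p rose by 6.63 ± 0.24, miR-296-5p by 5.90 ± 0.23 and miR-708 by 5.86 ± 0.22 on the log2 scale (SE). miR-31-5p rose by 5.38 ± 0.38, miR-148a by 5.14 ± 0.36, miR-181a-1* by 4.99 ± 0.23 and miR-187 by 4.97 ± 0.19. Among the largest falls besides the miR-199 and miR-214 arms, miR-137 changed by -7.87 ± 0.34, miR-130a by -7.84 ± 0.50 and miR-143 by -6.27 ± 0.29. miR-335-3p and miR-335-5p changed by -6.66 ± 0.24 and -6.39 ± 0.31. miR-199a-3p and miR-199b-3p have the same sequence and their reads cannot be assigned to either, so their log2 changes of -8.65 and -8.58 rest on parts of the same reads.

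In the cluster on the X chromosome that holds the miRNAs of the vectors, 10 of 11 tested members rose and 0 fell, with 10 and 0 adjusted over the list alone. miR-503 rose from 433.1 to 1943 RPM (2.14 ± 0.24 on the log2 scale), miR-424 from 1404 to 2833 and miR-542 from 169 to 368. With median-of-ratios scaling the calls of miR-424, miR-542 and miR-542* were lost, as was that of miR-450b, at log2 changes of 0.51, 0.67, 0.63 and 0.85. Without a filter, which tests more miRNAs, miR-424 and miR-542 kept log2 changes of 1.02 and 1.17 but lost their calls. The call of miR-424 was also lost without miR-450a vector replicate 2 (0.79) or 3 (1.09) and without empty vector replicate 2 (0.78) or 3 (1.02). That of miR-542 was lost without miR-450a vector replicate 2 (1.22) or 3 (0.99) and without empty vector replicate 1 (1.02) or 2 (0.93). The list includes the vector's own products. Camera called it up with them (adjusted p = 0.0289, and adjusted p = 0.181 with an estimated correlation). Without the miR-450a and miR-450b arms, 6 of 6 tested members rose, with a median log2 change of 1.13, and camera did not call the list (adjusted p = 0.118, and adjusted p = 0.254 with an estimated correlation). For the let-7 family, 10 of 15 tested members rose and 1 fell, with 11 and 1 adjusted over the list alone. let-7d rose from 42.2 to 719 RPM, let-7f by 3.57 ± 0.30 and let-7g by 3.55 ± 0.28, whereas let-7c was at -0.64 (adjusted p = 0.160). The let-7 list had a camera adjusted p of 0.0289, and adjusted p = 0.467 with an estimated correlation.

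Among miRNAs linked to p53, 3 of 9 tested members rose and 6 fell, with 3 and 6 adjusted over the list alone. miR-34a, a transcriptional target of p53, fell from 1878 to 460.4 RPM and miR-192 rose from 276 to 1231 (camera adjusted p = 0.0289, adjusted p = 0.152 with an estimated correlation). For the list of fibroblast, smooth muscle and endothelial miRNAs, 0 of 12 tested members rose and 10 fell, with 0 and 10 adjusted over the list alone (camera adjusted p = 2.68e-09, adjusted p = 0.0150 with an estimated correlation). The members were both arms of miR-126, miR-143, miR-145, miR-199a, miR-199b and miR-214. The genes of miR-143 and miR-145 are neighbours, as are those of miR-214 and a copy of miR-199a, so the 10 falls are not independent. Neither arm of miR-126, an endothelial miRNA, passed the test, and miR-143 and miR-145 are members of this list and of the p53-linked list. In the muscle list, where miR-1 and miR-133a have neighbouring genes, 0 of 3 tested members rose and 2 fell, with 0 and 2 adjusted over the list alone. There miR-1 changed by -3.65 ± 0.28 and miR-133a by -3.79 ± 0.35 (camera adjusted p = 0.0289, adjusted p = 0.152 with an estimated correlation). For the p53-linked and muscle lists the estimated correlation was -0.0593 and -0.142, below the preset 0.01. Their weaker p-values with it are therefore no sign that the members varied together. In the neural list, 3 of 7 tested members rose and 2 fell, with 3 and 2 adjusted over the list alone, with miR-9 at 3.42 and miR-137 at -7.87 (camera adjusted p = 0.947). The miR-17~92 cluster and its paralogs held 43.4 ± 3.83% of reads with the miR-450a vector and 25.1 ± 1.92% with the empty vector (SD, n = 3), and 6 of 25 tested members rose and 6 fell, with 6 and 6 adjusted over the list alone (camera adjusted p = 0.243). Its median log2 change was 0.04 and its mean -0.29. miR-92a, the most abundant miRNA over the 9 libraries, rose from 76473 to 203322 RPM, and miR-17 was at 0.61 (adjusted p = 0.128), which passed only without empty vector replicate 1 (0.83).

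In the list of miRNAs linked to energy metabolism, 3 of 17 tested members rose and 5 fell, with 3 and 5 adjusted over the list alone (camera adjusted p = 0.118), with miR-103 at 0.54 and miR-378 at 0.93. miR-143, at -6.27, is in this list as well as in the p53-linked and fibroblast, smooth muscle and endothelial lists. The median log2 change of the energy metabolism list was -0.11 and its mean -0.60. The call of miR-378 was lost with median-of-ratios scaling (0.42), without miR-450a vector replicate 1 (0.82) or 3 (0.91), and without empty vector replicate 1 (0.63). Among other X-linked miRNAs, 9 of 40 tested members rose and 6 fell, with 8 and 6 adjusted over the list alone (camera adjusted p = 0.432), and miR-221 and miR-222 rose from 9175 to 25674 RPM and from 3718 to 10323 RPM. The X-linked list shares miR-106a, miR-18b, miR-20b and miR-363 with the miR-17~92 list. In the miR-15 and miR-16 seed family outside the cluster, 2 of 10 tested members rose and 1 fell, with 2 and 0 adjusted over the list alone (camera adjusted p = 0.566), with miR-16 at -0.31. In the blood cell and serum list, 1 of 5 tested members rose and 0 fell, with 1 and 0 adjusted over the list alone (camera adjusted p = 0.848), with miR-142-3p at -0.26. In the miR-200 family, miR-200c rose from 62.0 to 286 RPM and miR-141 was at 0.52, a difference that passed only without empty vector replicate 1 (0.75). No member of the 14q32 cluster, C19MC, the miR-302 and miR-371 families or the liver list reached a mean of 10 RPM. Over the 9 libraries, miR-450a vector libraries correlated with empty vector libraries at r = 0.65 to 0.74 across miRNAs and with miR-450b vector libraries at r = 0.72 to 0.74, against 0.89 to 0.96 between the empty and miR-450b vector libraries. miRNAs are not independent replicates. With median-of-ratios scaling, the members that rose and fell numbered 6 and 0 in the cluster, 10 and 3 in the let-7 family, 1 and 7 in the miR-17~92 list and 3 and 7 among other X-linked miRNAs. They numbered 1 and 5 in the energy metabolism list, 0 and 2 in the miR-15 and miR-16 family, 0 and 3 in the muscle list and 1 and 1 in the blood list, and the camera call of the p53-linked list was lost (adjusted p = 0.0796).

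Fry, which tests whether the members of a list move on balance in 1 direction and does not compare them with other miRNAs, called 6 of the 11 lists with the miR-450a vector. The lists of energy metabolism (adjusted p = 0.00151), p53-linked (adjusted p = 4.93e-06), muscle (adjusted p = 4.93e-06) and fibroblast, smooth muscle and endothelial miRNAs (adjusted p = 1.19e-07) were lower on balance, and the cluster (adjusted p = 4.93e-06) and let-7 lists (adjusted p = 6.01e-05) higher. Of these, camera did not call the energy metabolism list. Fry called neither the miR-17~92 (adjusted p = 0.143), blood (adjusted p = 0.482), X-linked (adjusted p = 0.808) and neural lists (adjusted p = 0.808) nor the miR-15 and miR-16 family (adjusted p = 0.808). Without the miR-450a and miR-450b arms the cluster list kept its fry call (adjusted p = 1.41e-05). With median-of-ratios scaling fry also called the miR-17~92 (adjusted p = 0.00195), X-linked (adjusted p = 0.00208) and neural lists (adjusted p = 0.00165), all lower on balance. The miR-15 and miR-16 family was called lower there too (adjusted p = 0.0216). Whether fry called these lists thus depended on the scaling.

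**Figure D2:**
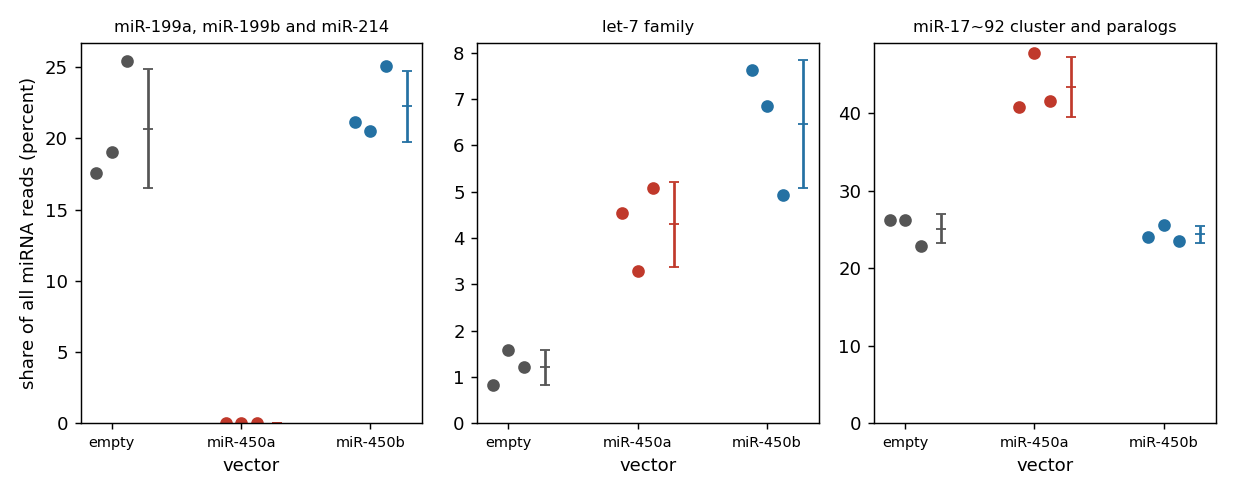
Share of all miRNA reads, in percent, held by miR-199a, miR-199b and miR-214, by the let-7 family and by the miR-17~92 cluster and paralogs, with 1 point per library and the mean ± SD of each group of 3 beside it. The first group held 0.0464 ± 0.00735% with the miR-450a vector and 22.2 ± 2.46% with the miR-450b vector, and let-7 held 1.21 ± 0.377% with the empty vector, below every library of both other groups.

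With the miR-450b vector, the question again being which other miRNAs differ, let-7 miRNAs were higher and miR-34a, miR-221 and miR-222 lower than with the empty vector. The let-7 family held 6.46 ± 1.38% of miRNA reads against 1.21 ± 0.377% with the empty vector (SD, n = 3). let-7a rose from 4818 ± 1588 to 32386 ± 7672 RPM and let-7b from 77.0 ± 29.9 to 1131 ± 231. miR-34a fell from 1878 ± 88.6 to 73.1 ± 15.7 RPM. miR-221 and miR-222, neighbours on the X chromosome, fell from 9175 ± 2349 to 1532 ± 427 and from 3718 ± 857 to 538 ± 191. Because each group carries a single vector, a response to miR-450b cannot be told apart from another difference of the cells.

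Of the 406 mature miRNAs, 59 passed the threshold, 18 higher and 41 lower with the miR-450b vector. The groups did not overlap for 129 (31.8%, where chance gives 10%). With median-of-ratios scaling 43.3% of the calls were higher, against 30.5% as deposited, and the median log2 change moved from -0.16 to -0.02. Apart from let-7 members and the miR-450b arms, miR-383 was among the 10 largest rises, by 3.48 ± 0.27 on the log2 scale (SE). let-7g rose by 2.70 ± 0.28, let-7d by 2.67 ± 0.30, let-7i by 2.55 ± 0.31, let-7c by 2.42 ± 0.36 and let-7f by 2.24 ± 0.30. The largest falls were miR-34a at -4.52 ± 0.34, miR-582 at -3.74 ± 0.26 and miR-629 at -3.64 ± 0.29. miR-145 followed at -3.09 ± 0.37, miR-551b at -2.98 ± 0.60, miR-148a at -2.89 ± 0.36, miR-335-3p at -2.85 ± 0.24 and miR-34a* at -2.75 ± 0.41. miR-551b no longer passed with a pseudocount of 100 RPM, at -1.04.

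Across the fixed lists, for the let-7 family 12 of 15 tested members rose and 0 fell, with 15 and 0 adjusted over the list alone (camera adjusted p = 9.80e-19, adjusted p = 0.0186 with an estimated correlation). For miRNAs linked to p53, 0 of 9 tested members rose and 6 fell, with 0 and 6 adjusted over the list alone (camera adjusted p = 4.67e-05, adjusted p = 0.0186 with an estimated correlation). The members that fell were both arms of miR-34a, of miR-143 and of miR-145, while miR-192 was at -0.51. The genes of miR-143 and miR-145 are neighbours, so these 6 falls are not independent. In the X-linked list, 0 of 40 tested members rose and 12 fell, with 0 and 14 adjusted over the list alone (camera adjusted p = 1.55e-04, adjusted p = 0.0551 with an estimated correlation). For the cluster of the vectors, 2 of 11 tested members rose and 0 fell, with 2 and 0 adjusted over the list alone, namely the miR-450b arms, and miR-424 was at -0.34, miR-503 at 0.06 and miR-542 at 0.08 (camera adjusted p = 0.00824, adjusted p = 0.123 with an estimated correlation). Without the miR-450a and miR-450b arms, 0 of 6 members rose and camera did not call the list (adjusted p = 0.492, and adjusted p = 0.573 with an estimated correlation). In the muscle list, 0 of 3 tested members rose and 3 fell, with 0 and 3 adjusted over the list alone (camera adjusted p = 0.00549, adjusted p = 0.0551 with an estimated correlation), with miR-1 at -2.12 and miR-133a at -2.65. The genes of miR-1 and miR-133a are neighbours, so these falls are not independent either. In the list of fibroblast, smooth muscle and endothelial miRNAs, 0 of 12 tested members rose and 4 fell, with 1 and 4 adjusted over the list alone (camera adjusted p = 0.185), the falls being the arms of miR-143 and miR-145, and miR-199a-3p was at 0.26.

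In the miR-17~92 list, 0 of 25 tested members rose and 7 fell, with 0 and 7 adjusted over the list alone (camera adjusted p = 0.173), with miR-92a at 0.60 and miR-17 at -0.40. For the neural list, 0 of 7 tested members rose and 2 fell, with 1 and 2 adjusted over the list alone (camera adjusted p = 0.830), with miR-137 at -0.50 and miR-128 at -0.08. The energy metabolism list had 0 rises and 2 falls among 17 tested members (camera adjusted p = 0.610), with miR-103 at 0.12 and miR-378 at 0.37. miR-143, also a member of the energy metabolism list, was at -2.18. No member passed the limma test in the miR-15 and miR-16 family outside the cluster (10 tested, camera adjusted p = 0.696) or in the blood cell and serum list (5 tested, camera adjusted p = 0.696), where miR-16 was at -0.47 and miR-142-3p at -0.06. miR-200c was at 0.84 (adjusted p = 0.104), and passed with median-of-ratios scaling (1.05) and without miR-450b vector replicate 3 (1.12), and miR-141 at -0.49. miR-10a, among the 5 most abundant miRNAs, was at 0.40 with the miR-450b vector and at 0.14 with the miR-450a vector. With median-of-ratios scaling the members that rose and fell numbered 14 and 0 in the let-7 family, 1 and 4 in the miR-17~92 list, 0 and 9 among other X-linked miRNAs, 0 and 2 in the muscle list, 1 and 4 in the fibroblast, smooth muscle and endothelial list and 1 and 1 in the neural list. With that scaling and an estimated correlation the X-linked and muscle lists were called too (adjusted p = 0.0369 and adjusted p = 0.0483). Fry called 8 of the 11 lists, 3 of them not called by camera. Those 3, all lower on balance, were the fibroblast, smooth muscle and endothelial (adjusted p = 0.00201), miR-17~92 (adjusted p = 0.0150) and energy metabolism lists (adjusted p = 0.0200). The other fry calls were the let-7 (adjusted p = 4.05e-05), p53-linked (adjusted p = 6.72e-06), X-linked (adjusted p = 2.22e-04), muscle (adjusted p = 4.05e-05) and cluster lists (adjusted p = 0.00499), of which the let-7 and cluster lists were higher and the others lower. The cluster list lost its fry call without the miR-450a and miR-450b arms (adjusted p = 0.304). Fry did not call the neural (adjusted p = 0.0591) and blood lists (adjusted p = 0.208) or the miR-15 and miR-16 family (adjusted p = 0.118). With median-of-ratios scaling the fry calls of the miR-17~92 (adjusted p = 0.0677) and energy metabolism lists (adjusted p = 0.175) were lost.

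The vector groups were compared to ask where cells with either vector differ from each other. miR-214-3p was lower with the miR-450a vector than with the miR-450b vector, with a log2 difference of -9.03, and miR-199a-3p, miR-199a-5p, miR-199b-5p and miR-137 were lower too, at -8.90, -8.69, -7.08 and -7.37. miR-675 and miR-675*, made from the H19 transcript, were lower, at -4.55 and -5.54. miR-148a was higher by 8.03, miR-629 by 7.54, miR-196b by 7.30, miR-30a by 6.33 and miR-31-5p by 5.87. Of 406 miRNAs, 245 passed the threshold, 170 higher and 75 lower with the miR-450a vector, and 280 did not overlap (69.0%, where chance gives 10%). With median-of-ratios scaling 45.9% of the calls were higher, against 69.4% as deposited, and the median log2 change moved from 0.62 to 0.01.

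miR-450a was higher with its own vector than with the miR-450b vector by 4.94 ± 0.37, and miR-450b differed by -1.87 ± 0.39 (log2, SE). miR-503 was higher by 2.08 ± 0.24. In the cluster list, 8 of 11 tested members were higher and 2 lower (camera adjusted p = 0.440), and without the miR-450a and miR-450b arms 5 of 6 were higher (camera adjusted p = 0.327). In the let-7 list, 7 of 15 were higher and 6 lower with the miR-450a vector (camera adjusted p = 0.409), and its median was 0.57 where its mean was -0.25. let-7c differed by -3.05 ± 0.36 and let-7f by 1.33 ± 0.30, and with median-of-ratios scaling 0 members were higher and 7 lower. The same scaling left 4 higher and 2 lower in the cluster list. miR-34a was higher by 2.41 ± 0.34, miR-221 by 4.08 ± 0.31 and miR-222 by 4.29 ± 0.32. The list of fibroblast, smooth muscle and endothelial miRNAs had 9 of 12 members lower and none higher in this comparison (camera adjusted p = 5.58e-08, adjusted p = 0.0230 with an estimated correlation), and it was the only list of the 11 tested that camera called. Fry called 4, this list (adjusted p = 4.55e-07) and the cluster (adjusted p = 5.67e-05), X-linked (adjusted p = 7.42e-04) and muscle lists (adjusted p = 0.0120), of which the cluster and X-linked lists were higher with the miR-450a vector and the others lower. The cluster list kept its fry call without the miR-450a and miR-450b arms (adjusted p = 4.43e-05). Fry did not call the p53-linked (adjusted p = 0.0678), neural (adjusted p = 0.0678), energy metabolism (adjusted p = 0.0981), blood (adjusted p = 0.0981), let-7 (adjusted p = 0.122) and miR-17~92 lists (adjusted p = 0.155) or the miR-15 and miR-16 family (adjusted p = 0.122). With median-of-ratios scaling the X-linked list lost its fry call (adjusted p = 0.148). Under that scaling the let-7 (adjusted p = 0.00343), energy metabolism (adjusted p = 7.13e-04) and neural lists (adjusted p = 0.00367) were called lower. So were the miR-17~92 (adjusted p = 0.0441) and p53-linked lists (adjusted p = 0.0449). As deposited, fry had placed the neural, miR-17~92 and p53-linked lists higher.

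In the table of precursors, the arms of a hairpin are counted together. Of 284 precursors tested, 178 passed the threshold between the miR-450a vector and the empty vector, 123 higher and 55 lower. Between the miR-450b vector and the empty vector 49 passed, 16 higher and 33 lower, and between the vectors 190 passed, 140 higher and 50 lower. With median-of-ratios scaling, the share of higher calls moved from 69.1% to 51.9% for the miR-450a vector against the empty vector (median log2 change 0.54 to -0.01). Between the vectors it moved from 73.7% to 50% (median 0.74 to -0.01). mir-450a-1 rose by 5.06 ± 0.34 and mir-450a-2 by 4.85 ± 0.36 with the miR-450a vector, with the reads of their common mature sequence split between them. mir-450b rose by 3.26 ± 0.38 with the miR-450b vector. The largest rises with the miR-450a vector were mir-196b at 7.54, mir-10b at 6.90 and mir-296 at 6.80, and the largest falls mir-214 at -9.08, mir-199a-1 at -8.70 and mir-199a-2 at -8.70. With the miR-450b vector, let-7b was at 3.74, mir-383 at 3.47, mir-34a at -4.56, mir-582 at -3.80 and mir-629 at -3.68.

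Because both vectors were compared with the same empty vector libraries, their changes share the chance values of those libraries. Over 401 miRNAs, without the miR-450a and miR-450b arms, the log2 changes of both comparisons correlated at r = 0.25, with a covariance of 0.525. Simulated unchanged groups against the same controls gave a mean r of 0.51 (0.36 to 0.62 in 100 simulations) and a mean covariance of 0.0625, which leaves 0.462. In both comparisons 9 miRNAs were called higher, 20 lower and 15 in opposite directions, where lists drawn independently would share 5.83, 7.67 and 17.9. Part of the excess may come from the shared controls, which are too few to split. Members called higher in both included let-7a, let-7b and let-7d, and members called lower in both included miR-34a, miR-335-3p and miR-145. miR-629, miR-148a, miR-221 and miR-222 went in opposite directions.

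**Figure D3:**
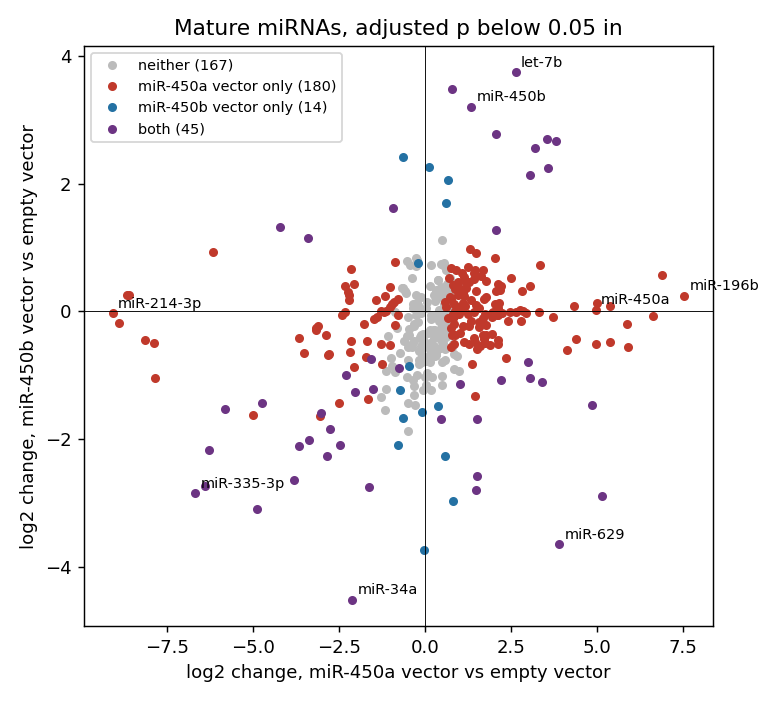
Log2 change of each of the 406 mature miRNAs with the miR-450a vector (horizontal axis) and with the miR-450b vector (vertical axis), each against the empty vector, with 1 point per miRNA coloured by the comparisons in which its adjusted p was below 0.05. miR-214-3p lies at -9.06 and -0.03, let-7b at 2.64 and 3.74, and miR-629 at 3.90 and -3.64.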

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

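Apart from the test of the 5p arm of the SV40 miRNA and the counts over other splits, the tests in this part were chosen after the results were seen. The SV40 miRNA miR-S1-5p, outside the comparisons because of its low level, stood at 0.833 ± 0.185 RPM in the miR-450a vector libraries (SD, n = 3). This was above its level in the control libraries, 0.0110 ± 0.0191 with the empty vector. In the miR-450b vector libraries it was 0.0953 ± 0.165. The other arm, miR-S1-3p, stood at 63.8 ± 13.95 RPM with the miR-450a vector, 0.0889 ± 0.154 with the empty vector and 0.167 ± 0.289 with the miR-450b vector. Of the viral rows below the filter, 95 were above 0 in some library, and 2 had all 3 libraries of a vector group above all 3 control libraries. Regrouping the 6 libraries of each row and vector group at random gives 1.60 such cases on average, close to the number seen. Besides miR-S1-5p, the case seen was mouse cytomegalovirus miR-M87-1, at 0.682 ± 0.447 RPM with the miR-450b vector, 0.164 ± 0.0655 with the empty vector and 1.02 ± 0.978 with the miR-450a vector.

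The miR-450a vector libraries differed from both other groups in most miRNAs tested. A partial admixture of other cells' RNA to unchanged A2780 RNA would leave every abundant miRNA at or above the share of A2780 RNA. Of the 25 miRNAs above 10000 RPM with the empty vector, 6 stood below 5% of that level, the lowest, miR-214-3p, at 0.136%, which argues against it. A candidate explanation, raised by the 3p arm of the SV40 miRNA, is RNA of another cell line that carries SV40 sequence, in place of A2780 RNA. The 5p arm, looked at afterwards, also lay above every other library in 3 of the 3 miR-450a vector libraries, though near the lowest values measured. Both arms come from the same hairpin, so any source of SV40 reads would give both. The test could therefore not decide whether that source was another cell line. No human miRNA profile of such a line was compared. A response of the A2780 cells to miR-450a alone would not bring in SV40 miRNA reads. miR-S1-3p stood at 63.8 ± 13.95 RPM with the miR-450a vector, against means of 0.0889 with the empty vector and 0.167 with the miR-450b vector. These reads argue against such a response as the only difference of these libraries. For the other miRNAs, a response, with 55.4% of the miRNAs tested past the threshold, cannot be told apart from a difference of the cells, because each group carries a single vector.

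Of 15 let-7 members tested, 10 rose and 1 fell with the miR-450a vector (10 and 3 with median-of-ratios scaling; camera adjusted p = 0.467 with an estimated correlation), and 12 rose and 0 fell with the miR-450b vector. Scaling to the total of miRNA reads does not account for the higher median of the list, as its log2 change stayed at 1.56 or more in both comparisons with median-of-ratios scaling. A property of the empty vector libraries alone was to be set aside if more than 50% of the let-7 members tested differed between the vector groups, and 86.7% did. That bound was wrong for these groups, which differed in 60.3% of all miRNAs, a reading adopted after the value was seen, so such a property cannot be told apart from a response to the vectors. A response to miR-450a or miR-450b stays open and was not tested. For the miR-450a vector, whether the libraries hold A2780 RNA is unsettled, so a difference of the cells stays open there too.

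A row for a turkey herpesvirus miRNA, miR-H14*, passed the filter and followed human miR-221. Its level ran from 1.32 to 57.0 RPM over the 9 libraries, while its ratio to miR-221 ran from 0.121% to 0.202%. miR-221 ranked 1 of 403 human rows in the steadiness of its log2 ratio to that row (SD 0.158), but miR-221* and miR-222 of the same locus ranked 2 and 3 (SD 0.185 and 0.287). miRNAs of one locus can follow each other whatever the source of the viral row. The ranks could therefore not tell reads of miR-221 assigned to the viral row apart from another link to that locus. No biological explanation was tested.

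Splits of the 6 libraries of each comparison into groups of 3 number 10 with the real split, too few for a share under 0.05. Every other split mixes libraries of both vectors, so a difference between the vectors widens the spread within its groups. Counts of 0 in these splits therefore do not show how many calls chance would give. For mature miRNAs, 1 of the 10 splits gave as many calls in each comparison. The miR-450a vector against the empty vector gave 225 calls in the real split and 0 in the highest other, the miR-450b vector 59 and 0, and the vectors against each other 245 and 0. With precursors, 1 of the 10 splits gave as many calls in each comparison. The real splits gave 178, 49 and 190 calls in the same order, and the highest others 0, 0 and 0.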

How the results depend on the processing

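The alternatives were fixed before the data were examined, except those that pair another fit with an estimated correlation and the cluster list without the vectors' own arms, chosen after seeing the data. Without these arms camera no longer called the cluster list for either vector against the empty vector, as the list lost the vectors' own products. Counts of mature calls moved by over 1.5 times only with the filter. With a mean of at least 100 RPM, which tests fewer miRNAs, they were 1.4e+02 to 2 significant digits (81 higher and 56 lower) for the miR-450a vector against the empty vector, 38 for the miR-450b vector against the empty vector and 140 between the vectors, with 125 precursors between the vectors. Without a filter the miR-450a vector gave 341, as more rows were tested. With an estimated correlation camera called 1 list for the miR-450a vector and 2 for the miR-450b vector, against 5 each. With median-of-ratios scaling and an estimated correlation it called 1, 4 and, between the vectors, 1. miR-450b with the miR-450a vector lost its call with median-of-ratios scaling (0.85, the cause was not tested) and without miR-450a vector replicate 3 (fewer samples), and leaving out each library gave 1.20 to 1.60. The rises of miR-450a and miR-450b with their own vectors kept their calls in each alternative run for them. Without the miR-450a vector libraries, the miR-450b vector gave 68 mature calls. Of the alternative values of single miRNAs, 2592 kept their side of the threshold, 55 lost it, 12 gained it and 0 reversed. The precursor table gave the same shares of miR-450a and miR-450b. The replicate numbers were not taken to pair the libraries, because not every same-numbered pair deviated together, with correlations from -0.51 to 0.64. As a hint from the data the other way, 6 of 9 libraries correlated best with their own number, where chance gives 3. With the replicate block, the mature calls were 230, 58 and 251. Under the block miR-424 with the miR-450a vector kept its log2 change of 1.02 and lost its call, and between the vectors miR-92a (0.83) lost its call and miR-542* (0.77) gained one. Camera at the preset correlation called 5, 5 and 1 lists with the block, but 0, 0 and 0 with the block and an estimated correlation, and the cause was not tested. There the fibroblast, smooth muscle and endothelial list had adjusted p = 0.119 for the miR-450a vector and adjusted p = 0.153 between the vectors, and the let-7 and p53-linked lists had adjusted p = 0.0982 and adjusted p = 0.0982 for the miR-450b vector. Fry with the block also called the p53-linked (adjusted p = 0.0413) and neural lists (adjusted p = 0.0123) between the vectors. For the miR-450b vector it also called the neural list (adjusted p = 0.0495). A count-based test was not run, since the values are shares, and the unknown depth limits what low miRNAs can show.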

Other observations

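The tests of neighbouring precursors below were chosen after the mature values were seen. miRNAs outside the fixed lists also moved with the miR-450a vector, and the following were picked after their values were seen. miR-181a stood at 4978 ± 816 RPM with the miR-450a vector and 491 ± 155.1 with the empty vector, and miR-30a at 1744 ± 304 and 53.1 ± 25.3 (SD, n = 3). Their log2 changes were 3.35 ± 0.34 and 4.85 ± 0.31 in the limma fit (SE, adjusted p = 7.60e-06 and 1.16e-07). miR-21, abundant in many carcinoma lines, stood at 5087 ± 1368 and 24295 ± 9985, and miR-29a at 3397 ± 476 and 29327 ± 2692, with log2 changes of -2.21 ± 0.37 and -3.11 ± 0.23 (SE, adjusted p = 3.61e-04 and 4.34e-07). A row for the HIV-1 TAR element, found in lentiviral long terminal repeats, stood at 210.3 ± 8.14 RPM with the empty vector, 274 ± 118 with the miR-450a vector and 189 ± 111 with the miR-450b vector.

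Precursors near each other on a chromosome tended to change together, a hypothesis tested on 118 pairs within 10000 bases in the GRCh38.p14 gene table, leaving out pairs of gene copies of one mature miRNA. With the miR-450a vector the median difference in log2 change of neighbours was 0.779, against a median of 2.001 when the changes were shuffled among the 98 precursors (permutation p = 0.0001, the smallest that 10000 shuffles can give). With the miR-450b vector it was 0.483 against 0.987 (permutation p = 0.0001). The pairs include 15 of paralogs with the same miRNA number, such as mir-29a and mir-29b-1. Without these, the remaining pairs gave 0.790 against 1.74 with the miR-450a vector (permutation p = 0.0001) and 0.489 against 0.900 with the miR-450b vector (permutation p = 0.0002). This is consistent with changes in shared primary transcripts, but miRNAs of similar sequence can share reads, and the pairs include members of the same cluster, so they are not independent.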
